A study of Homo sapiens with 12 samples.

How the data were processed

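PolyA RNA of HCT116 cells was sequenced from 12 libraries, 4 groups of 3 labelled replicates, harvested 48 hours after seeding. Libraries were stranded and run with a 75 cycle kit, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.12, featureCounts 1.4.6, edgeR 3.8.6 and the hg19 genome build, without saying which step each served. The labels do not say whether replicates were separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

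The files are 3 tables of the authors' edgeR output, one per knockout against the parental line, per the file headers. They hold a log2 fold change and a mean log2 CPM made by the authors, a likelihood ratio score computed by the authors, and a p-value with its adjusted value, as deposited. All 3 list the same 12756 genes with the same mean log2 CPM to within 1e-09 for 12756 of them. The deposited p-values were checked to be chi-square tails of the deposited likelihood ratios with 1 degree of freedom, and the adjusted values to be Benjamini-Hochberg values over all genes. Per-sample counts were not used here, so the depth of each library is unknown, no test of replicates was made, and genes were called at the authors' adjusted p under 0.05. The design written before the data were examined provided for count tests, and these gave way to its form for fold change tables.

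Approximate standard errors were rebuilt as the absolute log2 fold change over the square root of the likelihood ratio. The double was compared with the ANKRD52 knockout by the difference of the log2 fold changes, with the mean of both squared standard errors as its variance since the parental level drops out, a normal test, and Benjamini-Hochberg adjustment over genes with a mean log2 CPM of at least 1. Tested on simulated data over 12756 genes, this recovered 54% of differences of 0.5 and 88% of differences of 1. The simulation took these standard errors, equal variances and normal noise as given, so it does not check them. Group levels were implied from the mean CPM and the 3 fold changes, on the assumption of 4 equal groups. Genes listed at 0 in a pair of tables put a group without reads at 0.00383 CPM, and with an assumed prior count of 0.125 a group with 3 reads lies at 0.0345 CPM. No fold is printed for genes under that level, a rule set after seeing the data.

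The 25 gene lists, the microRNA sites and the rule for named genes were fixed before the data were examined. A list's median log2 fold change was compared two-sided with 10000 random lists matched on deciles of mean expression, adjusted over lists and comparisons, and lists with fewer than 5 measured members were only described. The smallest p the random lists can give is 0.0002. They were not matched on 3' UTR length or GC content. This test is across genes, which are not independent replicates and move together, and a correlation between genes could not be estimated. Named were the targeted genes, the 10 largest rises and falls per comparison among called genes with a mean log2 CPM of at least 1, up to 4 members with the smallest p per list, the 5 largest differences each way between double and single, and the 5 genes each way changed most in all 3.

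3' UTRs were taken from GENCODE release 29 (GRCh38), with genes matched by name: 11838 by symbol, 594 by a RefSeq synonym and 324 not matched. The authors' build differs, so positions are those of GRCh38 and were used only for gene order. The 11322 genes with a mean log2 CPM of at least 1 and a 3' UTR of at least 50 bases were used. Their log2 fold change was regressed on presence of each 7-base sequence found in and missing from at least 50 genes. Log length, GC content and mean expression were covariates, and sequences were ranked by effect over standard error. On simulated data over 3000 genes a planted effect of 0.1 was estimated at 0.0846 (SE 0.0283). Shared parental libraries were simulated with 100 draws of unchanged groups, and, chosen after seeing the data, the overlap of lists of the observed sizes was counted in such draws. Alternatives were other thresholds, expression filters, centring, list statistics and site definitions, and, chosen after seeing the data, an F distribution, leaving out chromosome 7 and distal chromosome 8, limiting fold changes to -1 to 1 and ranking by effect, with all site alternatives, with and without that limit, of the effect averaged over the 18 families and of that effect less the control families. Work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.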

Results

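Polyadenylated RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, in 4 groups of 3 labelled replicates. The groups were the parental line, cells with a knockout of AGO2, cells with a knockout of ANKRD52, and cells with a double knockout of ANKRD52 and CSNK1A1. AGO2 is the Argonaute protein that carries microRNAs to their target messages, ANKRD52 is a regulatory subunit of the PP6 phosphatase, and CSNK1A1 is casein kinase 1 alpha. The title of the study names an Argonaute phosphorylation cycle in microRNA silencing, so the comparisons ask how loss of each factor changed the transcriptome. Each knockout was compared with the parental line over 12756 genes, and the values are the authors' own fold changes, with a log2 fold change above 0 meaning a higher level in the knockout. The libraries' read totals are not used here, so the depth of each library is unknown.

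The targeted genes were examined first. In the AGO2 knockout, AGO2 RNA fell by 1.07 on the log2 scale in the authors' deposited table (approximate standard error 0.36, adjusted p = 0.0477). AGO2 lies in a part of chromosome 8 whose 65 genes had a median of -0.53 in this knockout, so part of the fall may be shared with its neighbours. In the ANKRD52 knockout, ANKRD52 RNA had a log2 fold change of 0.03 (adjusted p = 0.915) in the authors' deposited table, so the RNA level did not separate this group from the parental line. In the double knockout, ANKRD52 fell by 0.65 (adjusted p = 2.32e-05) and CSNK1A1 fell by 2.42 (adjusted p = 1.71e-10), again from the authors' deposited table. An edit that shifts the reading frame can leave RNA in place, so these levels do not check protein loss. ANKRD52 RNA rose in the AGO2 knockout, with a log2 fold change of 0.85 (adjusted p = 8.78e-07) in the deposited table of the authors. The approximate standard errors of AGO2 and CSNK1A1, as medians over the 3 comparisons, were wider than those of 99.0% and 98.2% of genes of like expression.

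In the AGO2 knockout 12 of 25 measured p53 targets, 4 of 15 interferon-stimulated genes, 4 of 12 YAP/TEAD targets and 3 of 9 mesenchymal genes rose, and 8 of 13 cholesterol and lipid synthesis genes fell. The cell cycle inhibitor CDKN1A rose 2.52-fold, the p53 antagonist MDM2 1.48-fold and BTG2 1.74-fold in the authors' deposited table (adjusted p = 2.46e-13, 7.51e-05 and 1.30e-05). The intermediate filament gene VIM rose 5.93-fold and the transcription factor ZEB1, a classical target of the miR-200 family, rose by 1.58 on the log2 scale (adjusted p = 0.00175 and 0.0465) in the same authors' deposited table. DICER1, which cuts microRNA precursors and is itself a let-7 target, rose 1.71-fold (adjusted p = 3.90e-13), and the let-7 target HMGA2 rose 2.29-fold (adjusted p = 2.51e-10), per the authors' deposited table.

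At an adjusted p under 0.05 the authors' deposited table held 778 changed genes for the AGO2 knockout, 431 higher and 347 lower. Their median absolute change was 1.41-fold. The largest rises in the authors' deposited table included the semaphorin receptor NRP1 (log2 fold change 3.70, adjusted p = 0.00671), the carboxypeptidase CPA4 (3.27, 2.09e-06), the adhesion molecule CEACAM1 (2.64, 8.14e-10), COL17A1 (2.15, 0.000104) and LOXL4 (1.99, 0.0461). The RNA sensor TLR3 and the interferon-induced IFIT3 rose by 1.93 and 1.64 in that authors' deposited table. The approximate standard error of NRP1 was 0.96 in the authors' deposited table, and the median errors of NRP1, VIM and ZEB1 over the 3 comparisons were wider than those of 99.8%, 99.1% and 98.7% of genes of like expression. ALPP was also among the 10 largest rises, but its implied parental level lay under that of 3 reads over the group, so no fold is given. The largest falls in the authors' deposited table were ANKRD37 (-1.69), the polyamine enzyme SAT1 (-1.56), IGSF9 (-1.30), CITED4 (-1.23), DLGAP1 (-1.11), ZNF251 (-1.06), KCNH8 (-1.06), the cholesterol enzyme SQLE (-1.05) and the transcription factor SOX4 (-1.05), beside AGO2 itself.

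Of 25 measured p53 targets, 12 rose and 0 fell (15 passed when adjusted over the list alone), with a median log2 fold change of 0.46 (adjusted p = 0.000825 against random lists matched on expression). Of 15 interferon-stimulated genes 4 rose, among them IFIT2 (1.55), IFIT1 (0.91) and OAS3 (0.42) in the authors' deposited table, with a list median of 0.42 (adjusted p = 0.000825; 6 adjusted over the list alone). Among 12 YAP/TEAD targets 4 rose, including CTGF (1.22) and NT5E (1.03) in the authors' deposited table (list median 0.61, mean 0.95, adjusted p = 0.000825; 9 adjusted over the list alone). Of 9 mesenchymal genes 3 rose (3 adjusted over the list alone), with a median of 0.69 (adjusted p = 0.000825). Of 13 cholesterol and lipid synthesis genes 8 fell and 0 rose (11 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.000825). Among them MVD stood at -0.62 in the authors' deposited table. Proliferation genes (2 fell and 0 rose of 19, 6 adjusted over the list alone, median -0.12) and epithelial genes (1 and 0 of 14, 3 adjusted over the list alone, median -0.16) lay below their random lists (adjusted p = 0.0156 and 0.0137), but not below unmatched random lists (adjusted p = 0.117 and 0.0770). Of 16 unfolded protein and amino acid stress genes 2 rose and 2 fell (7 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0193, or 0.241 with the mean in place of the median).

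Lists of known microRNA targets lay above their random lists in the AGO2 knockout for the miR-17 family (median 0.25, adjusted p = 0.00139), for miR-19 (0.27, 0.000825) and for let-7 (0.19, 0.0116). The random lists were not matched on 3' UTR length or GC content, which went with these fold changes (rank correlations 0.147 and -0.288). These calls therefore do not separate target status from either. Of the 22 miR-17 family targets 5 rose, and of the 13 miR-19 targets 0 passed over all genes (10 and 2 adjusted over the list alone). Of the 17 let-7 targets 3 rose (4 adjusted over the list alone). The targets of miR-200 (median 0.13, adjusted p = 0.0856), miR-15/16 (0.13, 0.0920) and miR-21 (0.05, 0.688) did not pass as lists. With the mean in place of the median the miR-200 and miR-15/16 lists did (adjusted p = 0.0342 and 0.04997).

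Genes on parts of chromosomes 7 and 8 differed together in the AGO2 knockout. Over the 65 genes of chromosome 8 from TRAPPC9 to its end (positions 139727725 to 145066685, GRCh38), which include AGO2, ZNF251 and EPPK1, the median log2 fold change was -0.53, against -0.15 in the ANKRD52 knockout and -0.28 in the double knockout. The start at TRAPPC9 was chosen after the values were seen, and windows of 40 genes that begin before it also lay low, at -0.27 from position 112222928 to 132675617 and -0.40 from 123319850 to 143359979 (SD over windows 0.0928). Both windows hold the cholesterol gene SQLE (start 124998497), which was among the largest falls. On chromosome 7 the median was -0.25 over 160 genes that start before position 55000000 and 0.20 over 304 genes after it, a division chosen after the values were seen. Referring the authors' likelihood ratios to an F distribution with 1 and 8 degrees of freedom, a stricter reading chosen after seeing the data, left 0 genes for this knockout (1834 at an unadjusted p under 0.05). An adjusted p under 0.01 left 274.

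**Figure D1:**
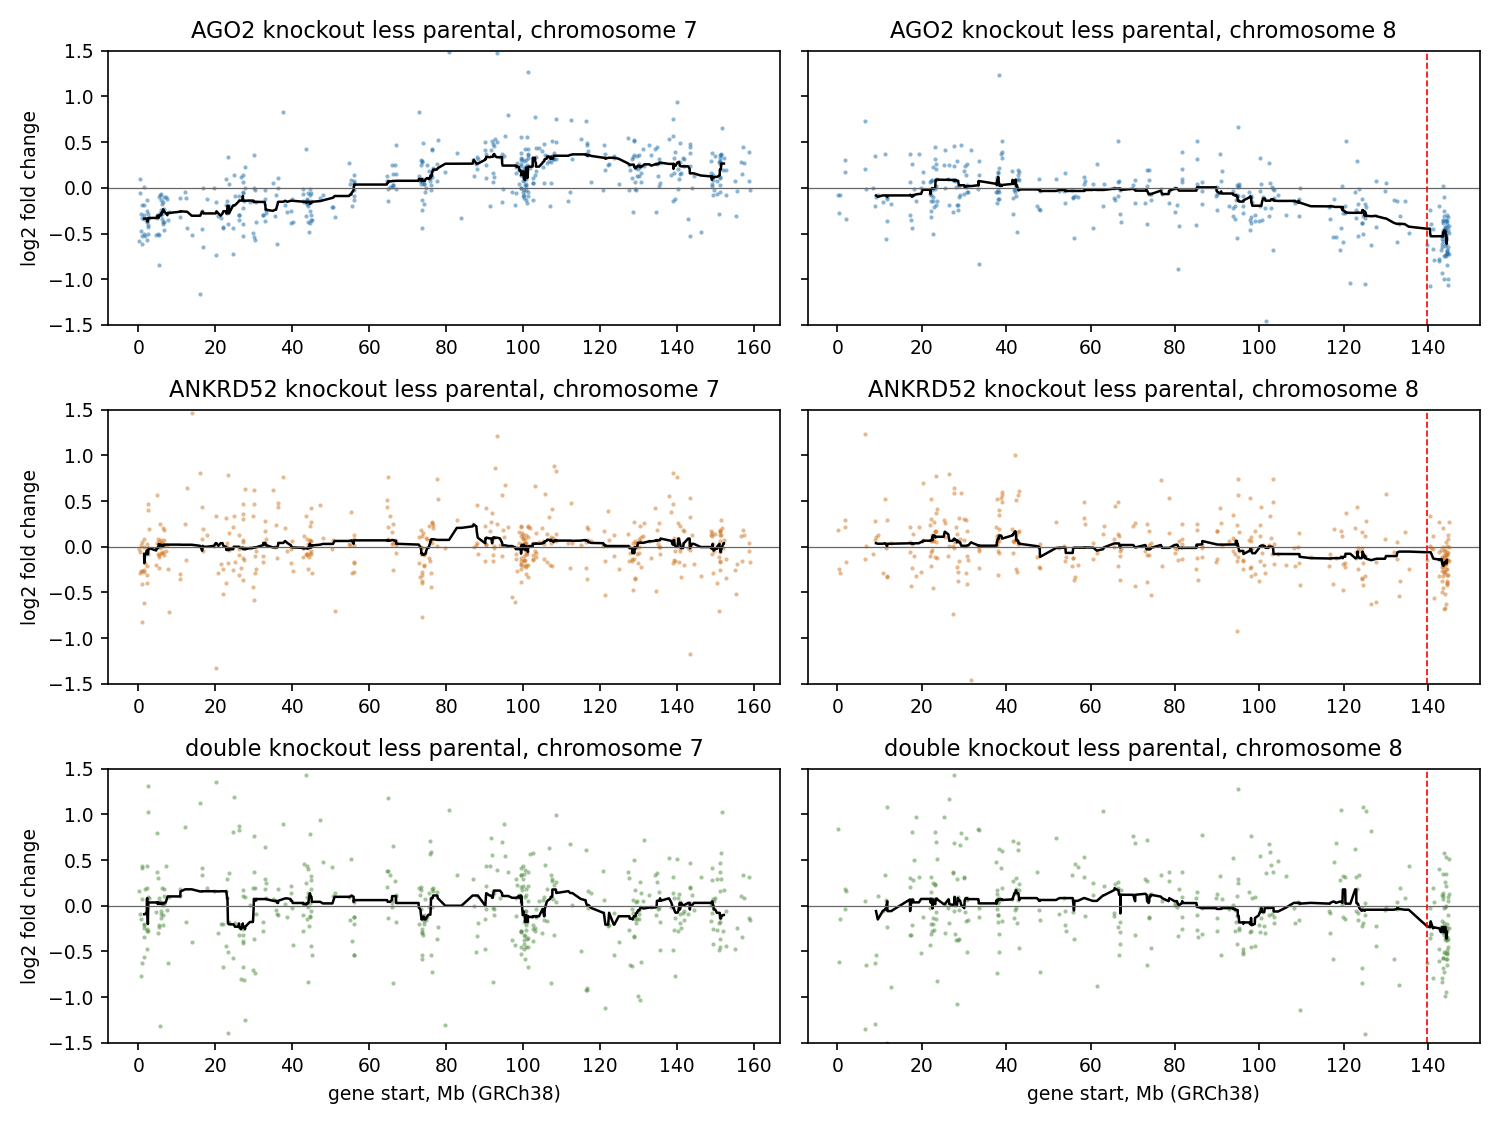
Log2 fold change of genes with a mean log2 CPM of at least 3 along chromosomes 7 and 8 (gene start in Mb, GRCh38) in each knockout less the parental line, with points for genes, a black line for the running median over 25 genes and a dashed line at the start of TRAPPC9. Points beyond 1.5 in size are not drawn. In the AGO2 knockout the genes right of the dashed line lie at a median of -0.53.

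In the ANKRD52 knockout 7 of 9 measured mesenchymal genes and 8 of 16 miR-200 family targets rose, and 6 of 14 epithelial genes fell. SPARC, a secreted matrix protein, rose by 8.04 on the log2 scale, VIM by 4.44 and ZEB1 by 2.78 in the authors' deposited table (adjusted p = 4.11e-10, 3.19e-09 and 3.43e-05). The epithelial splicing factor ESRP1 (-0.92), the tight junction gene CLDN7 (-1.22), EPCAM (-0.81) and the epithelial transcription factor GRHL2 (-2.03) fell in the authors' deposited table. HMGA2 rose 3.41-fold, DICER1 1.89-fold and the miR-200 target QKI 1.92-fold (adjusted p = 2.78e-23, 2.55e-19 and 5.11e-12) in the authors' deposited table. The scaffold genes of silencing TNRC6A (0.63), TNRC6B (0.43) and TNRC6C (0.41) rose in that authors' deposited table, among 4 of 13 microRNA biogenesis and Argonaute genes (4 adjusted over the list alone), a list that was not called (median 0.18, adjusted p = 0.0504). Of 23 deadenylation and decapping genes 1 rose, the decapping enzyme DCP2 (0.64) in the authors' deposited table, and the list was not called (median 0.02, adjusted p = 0.999; 1 adjusted over the list alone).

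The authors' deposited table for the ANKRD52 knockout held 1742 changed genes, 972 higher and 770 lower. Besides SPARC and VIM, its largest rises were ANKRD1 (5.64), CLDN2 (4.74), the hyaluronan synthase HAS2 (4.44), GRIK2 (4.09), SEMA3A (3.96) and TGFB2 (3.83), all log2 fold changes from the authors' deposited table. GPR55 and APOBEC3G were also among the 10, but their implied parental levels lay under that of 3 reads, so no fold is given. The largest falls in the authors' deposited table were TTN (-2.72), the glycosyltransferase GALNT3 (-2.39), ATP2C2 (-2.37), PRDM1 (-2.29), PROM2 (-2.20), AP1M2 (-2.05), GRHL2, ANKRD37, S100A14 (-1.96) and CCDC64B (-1.95). The spread behind some of these was wide: the approximate standard error was 1.12 for SPARC and 1.60 for ANKRD1 from the authors' deposited table.

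Of 9 mesenchymal genes 7 rose (7 adjusted over the list alone), with a median log2 fold change of 1.44 (adjusted p = 0.000825). That median was 0.84 over members with a mean log2 CPM of at least 1, and the mean of the list was 2.56. Of 16 miR-200 family targets 8 rose and 0 fell (8 adjusted over the list alone; median 0.34, mean 0.73, adjusted p = 0.000825), and the mesenchymal list shares ZEB1, ZEB2 and FN1 with it. Of 14 epithelial genes 6 fell and 0 rose (8 adjusted over the list alone; median -0.42, adjusted p = 0.000825). Interferon-stimulated genes (8 of 15 rose, 10 adjusted over the list alone, median 0.50, adjusted p = 0.000825) and YAP/TEAD targets (8 of 12 rose, 8 adjusted over the list alone, median 0.56, mean 1.24, adjusted p = 0.000825) lay above their random lists. Cholesterol genes fell in 7 of 13 cases (8 adjusted over the list alone, median -0.32, adjusted p = 0.000825). The p53 list was not called (8 members adjusted over the list alone, 3 rose and 3 fell, median 0.01, adjusted p = 0.984). The lists of let-7 (median 0.25, adjusted p = 0.00503), miR-17 (0.17, 0.0115), miR-19 (0.25, 0.0108) and miR-15/16 targets (0.20, 0.0116) lay above their random lists. Of these 4, 5, 4 and 2 members rose, and 1, 1, 0 and 2 fell (7, 8, 5 and 4 adjusted over the list alone). With the mean in place of the median the miR-19 and miR-15/16 lists were not called (adjusted p = 0.0545 and 0.130). None of these target lists, nor that of miR-200, had random lists matched on 3' UTR length or GC content. Both went with the fold changes of this knockout (rank correlations 0.238 and -0.177). Wnt/beta-catenin targets (3 rose and 1 fell of 17, 4 adjusted over the list alone, median 0.18, adjusted p = 0.0341) lost their call with the mean (adjusted p = 0.0800) and with unmatched random lists (0.0557). So did proliferation genes (0 rose and 1 fell of 19, 0 adjusted over the list alone, median -0.11, adjusted p = 0.0483, then 0.129 and 0.188). Stress genes (1 rose and 3 fell of 16, 5 adjusted over the list alone, median -0.15, adjusted p = 0.0356) lost theirs with unmatched random lists (adjusted p = 0.0820). The F distribution with 1 and 8 degrees of freedom left 3 genes for this knockout (2473 at an unadjusted p under 0.05), and an adjusted p under 0.01 left 874.

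In the double knockout 12 of 17 measured Wnt/beta-catenin targets and 21 of 25 p53 targets rose, and 12 of 13 cholesterol and lipid synthesis genes and 14 of 19 proliferation genes fell. AXIN2, a feedback inhibitor of Wnt signalling, rose 11.6-fold, SP5 11.7-fold, NKD1 8.22-fold and ZNRF3 5.03-fold (adjusted p = 2.58e-21, 1.14e-39, 1.26e-22 and 2.11e-49) in the authors' deposited table. MDM2 rose 2.90-fold, GDF15 2.76-fold, PHLDA3 4.58-fold and CDKN1A 2.10-fold (adjusted p = 6.99e-41, 1.43e-15, 3.16e-20 and 1.60e-10) in the authors' deposited table. INSIG1 fell by 2.64 on the log2 scale and the cholesterol regulator SREBF2 by 1.46 (adjusted p = 6.61e-122 and 6.81e-52), per the authors' deposited table. The replication licensing genes MCM5 (-0.86) and MCM4 (-0.73) and the cyclin CCNB1 (-0.46) fell in the authors' deposited table.

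This knockout changed 5486 genes in the authors' deposited table, 43.0% of those tested, 2919 higher and 2567 lower. Among the largest rises in the authors' deposited table were ANKRD1 (10.86) and PLEKHS1 (9.96). CSMD3, ARHGEF38, GPR55, KCNB2, TSPAN8, ALPP and APOBEC3G were also among them, but their implied parental levels lay under that of 3 reads, so no fold is given. The largest falls in the authors' deposited table were ANXA10 (-7.95), ARHGAP29 (-5.39), the vitamin D hydroxylase CYP24A1 (-4.48), TNFSF18 (-4.11), the nuclear receptor NR2F1 (-4.06), MALL (-4.02), SPOCK3 (-3.96), DPEP1 (-3.75) and HS3ST1 (-3.72). CSNK1A1P1 (-5.39) and CSNK1A1L (-2.76) also fell in the authors' deposited table, and both resemble CSNK1A1 in sequence, so their values are uncertain. Of 3 measured markers of other cell types 2 rose, LYZ by 6.77 and VWF by 2.25 on the log2 scale, and COL1A1 had 0.24 (adjusted p = 0.281) in the authors' deposited table.

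Of 17 Wnt/beta-catenin targets 12 rose and 2 fell (14 adjusted over the list alone), with a median log2 fold change of 1.24 (adjusted p = 0.000825). Of 25 p53 targets 21 rose and 0 fell (21 adjusted over the list alone; median 0.82, adjusted p = 0.000825). Of 13 cholesterol and lipid synthesis genes 12 fell and 1 rose (13 adjusted over the list alone; median -1.46, adjusted p = 0.000825). Of 19 proliferation genes 14 fell and 2 rose (16 adjusted over the list alone; median -0.37, adjusted p = 0.00139, or 0.0545 with the mean in place of the median). YAP/TEAD targets rose in 7 of 12 cases and fell in 3 (10 adjusted over the list alone, median 0.72, mean 1.44, adjusted p = 0.000825), among them CTGF at 2.94 and NT5E at -1.88 in the authors' deposited table. Of 9 mesenchymal genes 3 rose and 1 fell (4 adjusted over the list alone; median 0.97, adjusted p = 0.00462). The miR-21 target list passed (10 rose and 2 fell of 18, 12 adjusted over the list alone, median 0.27, adjusted p = 0.0464), but not with the mean in place of the median (adjusted p = 0.104) or with unmatched random lists (0.0770). The target lists of miR-17 (median 0.16, adjusted p = 0.0869), miR-19 (0.26, 0.107), let-7 (0.02, 0.832), miR-200 (0.04, 0.832) and miR-15/16 (-0.04, 0.832) did not pass.

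**Figure D2:**
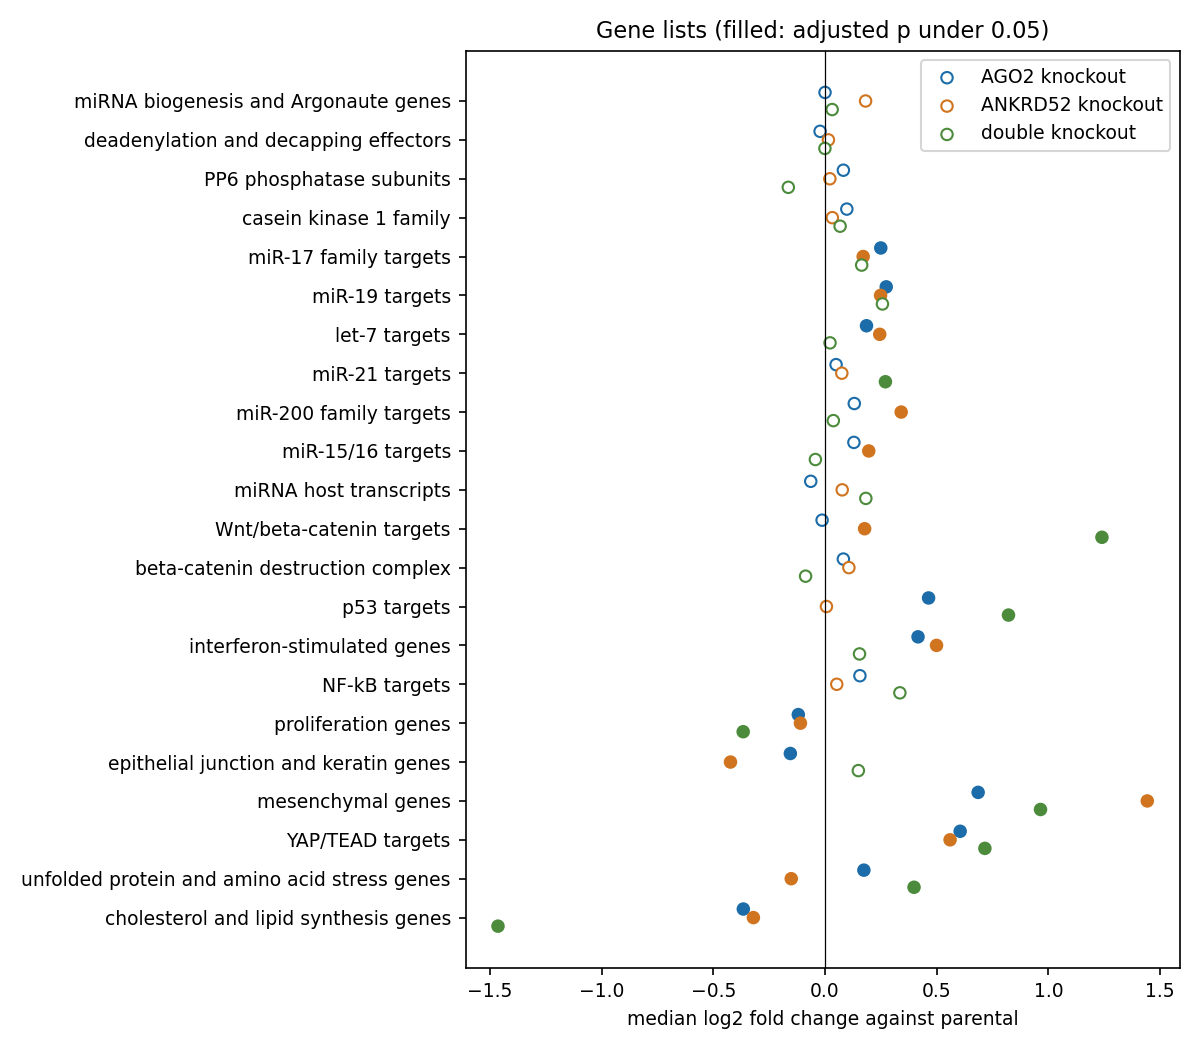
Median log2 fold change against the parental line of each gene list with at least 5 measured members, by knockout (blue, AGO2; orange, ANKRD52; green, double), with filled circles for an adjusted p under 0.05 against 10000 random lists. The Wnt/beta-catenin targets lie at 1.24 in the double knockout, and the mesenchymal genes at 1.44 in the ANKRD52 knockout (0.84 over members with a mean log2 CPM of at least 1).

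Set against the ANKRD52 knockout, 7 of 16 miR-200 family targets were lower in the double knockout and 2 higher, while 10 of 14 epithelial genes, 19 of 25 p53 targets and 10 of 17 Wnt/beta-catenin targets were higher. HMGA2 differed by -2.46 on the log2 scale, DICER1 by -0.88 and ZEB1 by -2.29 (approximate adjusted p = 1.38e-49, 1.47e-19 and 0.000146), as differences of fold changes in the authors' deposited tables. The miR-200 target list differed by -0.29 (adjusted p = 0.00691), the epithelial list by 0.75 (0.00110), the p53 list by 0.75 (0.00110), the Wnt list by 1.08 (0.00110) and the cholesterol list by -1.16 (0.00110). The proliferation list differed by -0.29 (adjusted p = 0.00587; 10 of 19 lower and 1 higher) and the stress list by 0.30 (0.00587; 8 of 16 higher and 0 lower). PP6 phosphatase subunits, a list that holds ANKRD52 itself, differed by -0.38 (adjusted p = 0.0319; 4 of 7 lower and 0 higher). For the lists of miR-17 (-0.0041, 0.833), miR-19 (0.01, 0.868), let-7 (-0.16, 0.276) and mesenchymal genes (0.13, 0.711) no difference passed. Within the mesenchymal list the members parted, with VIM differing by -3.34 and SPARC by 0.13 (approximate adjusted p = 6.48e-07 and 0.941) from the authors' deposited tables.

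Of 11877 genes with a mean log2 CPM of at least 1, 4093 differed between both knockouts, 2152 higher and 1941 lower in the double. Of 927 genes that rose in the ANKRD52 knockout, 298 were lower and 147 higher in the double, and 522 rose there as well. The slope of the double on the single log2 fold change over the 1662 called genes was 0.867. The parental libraries enter both fold changes, so part of this slope may come from them. Genes that rose had a median of 0.50 in the single and 0.37 in the double, and those that fell -0.44 and -0.37. Among genes called in the ANKRD52 knockout, the largest differences downward were TNFSF18 (-7.46), DRD1 (-3.40), VIM, SSTR5-AS1 (-3.08) and SAMD5 (-2.97), and upward PLEKHS1 (7.09), CEACAM1 (6.15), PRF1 (5.84), ANKRD1 (5.23) and HAS2 (5.13), from the authors' deposited tables. Genes chosen for a call drift toward 0 in a second comparison, so the same was asked, after the results were seen, of the 419 genes that rose in the AGO2 knockout, whose libraries do not enter the difference. Of these 116 were lower and 75 higher in the double than in the ANKRD52 knockout, with a median difference of -0.08. Of the 327 that fell in the AGO2 knockout, 73 were higher and 45 lower, with a median difference of 0.01.

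Among 11877 genes with a mean log2 CPM of at least 1, the AGO2 and ANKRD52 knockouts changed 201 genes upward and 114 downward in common, against 32.7 and 20.2 for independent lists, and 5 in opposite directions. Lists of the same sizes drawn from unchanged groups that share the parental libraries, a simulation chosen after seeing the data, had 151 (at most 175) and 109 (at most 130) in common, so the shared falls did not exceed it. Unchanged groups called at the same adjusted p shared 0 genes for each pair of knockouts, so lists of these sizes were forced on them. The forced lists therefore cannot decide how many shared calls come from the controls. The log2 fold changes correlated across genes with r = 0.498 (Spearman 0.484). Unchanged groups that share the parental libraries gave a simulated r of 0.499, so the correlation did not exceed what the shared controls give with no effect. Changes particular to 1 knockout lower r, so a shared effect is not excluded by this. The covariance was 0.0549 against a simulated 0.0170, and 68.2% of genes had the same sign against 66.7% simulated. Genes are not independent replicates, and the tables hold no per-sample values, so the controls could not be divided and part of the excess may come from them. Over the same genes the ANKRD52 and double knockouts shared 2.51 times as many rises and 2.78 times as many falls as independent lists would, with 112 genes opposite (r = 0.413, simulated 0.502; covariance 0.126, simulated 0.0172). They shared 4.40% of genes upward and 3.61% downward, against 4.53% and 3.58% for simulated lists of the same sizes (at most 4.82% and 3.85%), so neither exceeded these. The AGO2 and double knockouts shared 190 rises and 140 falls, against 94.2 and 68.7 for independent lists and 273 and 213 simulated, with 84 opposite (r = 0.2997, simulated 0.501; covariance 0.0712, simulated 0.0171). Of all 12756 genes, 0.831% rose and 0.666% fell in all 3 knockouts, against 0.0589% and 0.0330% for independent lists and 0.975% and 0.696% for the simulated lists. List sizes were forced on unchanged groups here too, so these shares do not decide between the shared controls and the knockouts. Those that rose most in all 3 were CEACAM1, TLR3, SAMD9, SECTM1 and CTGF, and those that fell ANKRD37, TMEM160, NUDT3, FAM131C and EPPK1, per the authors' deposited tables.

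In both single knockouts the 3' UTR sites of a few microRNA families ranked near the top of all 7-base sequences, a comparison across genes, which are not independent replicates. In the AGO2 knockout, genes with a site of the miR-17 family (GCACTTT) lay 0.0397 (SE 0.00668) above genes without on the log2 scale after adjustment for 3' UTR length, GC content and expression, rank 1 of 16220 7-base sequences. The sites of the miR-130 family (0.0292, rank 4), the miR-200bc family (0.0260, rank 7) and miR-19 (0.0241, rank 15) followed, and the sites of miR-19, miR-130 and miR-17 share bases. In the ANKRD52 knockout the site of miR-19 (0.0427, SE 0.00994) had rank 1, that of the miR-200bc family (0.0375, SE 0.00958) rank 2 and that of miR-29 (0.0297) rank 28, while that of miR-17 (0.0169, SE 0.00873) had rank 357. In the double knockout the same effects were 0.00891 (SE 0.0190) for miR-17, 0.00320 (SE 0.0217) for miR-19 and -0.00434 (SE 0.0209) for miR-200bc, and 0 of the 18 families were in the top 1% of sequences, a limit set after the ranks were seen. That was so for 4 families in the AGO2 knockout and 3 in the ANKRD52 knockout, and for 0 of 6 control families of other tissues in each. The let-7 site was not among them, at 0.0133 (SE 0.00860, rank 601) in the AGO2 and 0.00607 (SE 0.0112, rank 3223) in the ANKRD52 knockout. Nor was that of miR-15/16, at -0.00237 (SE 0.00652, rank 7001) and 0.01615 (SE 0.00851, rank 379). All 4 values lay within 2 standard errors of 0, so the called lists of these families had no such site effect beside them. In tests added after the ranks were seen, the effect averaged over all 18 families was 0.00840 (SE 0.00229) in the AGO2 and 0.0129 (SE 0.00299) in the ANKRD52 knockout. Less the control families it was 0.00995 (SE 0.00483) and 0.00814 (SE 0.00630), the latter within 2 standard errors of 0. In the AGO2 knockout this difference fell within 2 standard errors with 8-base sites (0.0138), 6-base sites (0.00246) and the shortest 3' UTRs (0.00718). It stayed over 2 without covariates, at a mean log2 CPM of at least 3 and without chromosome 7 and distal chromosome 8. With fold changes not limited, that of the ANKRD52 knockout passed 2 only with 6-base sites (0.00904) and without covariates (0.0175). For the double less the ANKRD52 knockout the mean was -0.0161 (SE 0.00597) over the 18 families and 0.00192 (SE 0.0120) over the control families, and their difference of -0.0180 (SE 0.0126) lay within 2 standard errors of 0. Without covariates the families turned to 0.00446 (SE 0.00815) and the controls to 0.0222 (SE 0.0130), with -0.0177 (SE 0.0121) between them. With 8-base sites they lay at -0.0245 and -0.0239, which left -0.000687 (SE 0.0207). With 6-base sites they lay at -0.00542 (SE 0.00492) and 0.0158 (SE 0.00721), and the difference of -0.0212 (SE 0.00786) was over 2 standard errors from 0. With the shortest 3' UTR per gene the families lay at -0.0122 (SE 0.00929), and -0.00232 (SE 0.0186) less the controls. Without covariates 1 family was in the top 1% in each single knockout, and in the ANKRD52 knockout 0 were when ranked by the difference itself.

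**Figure D3:**
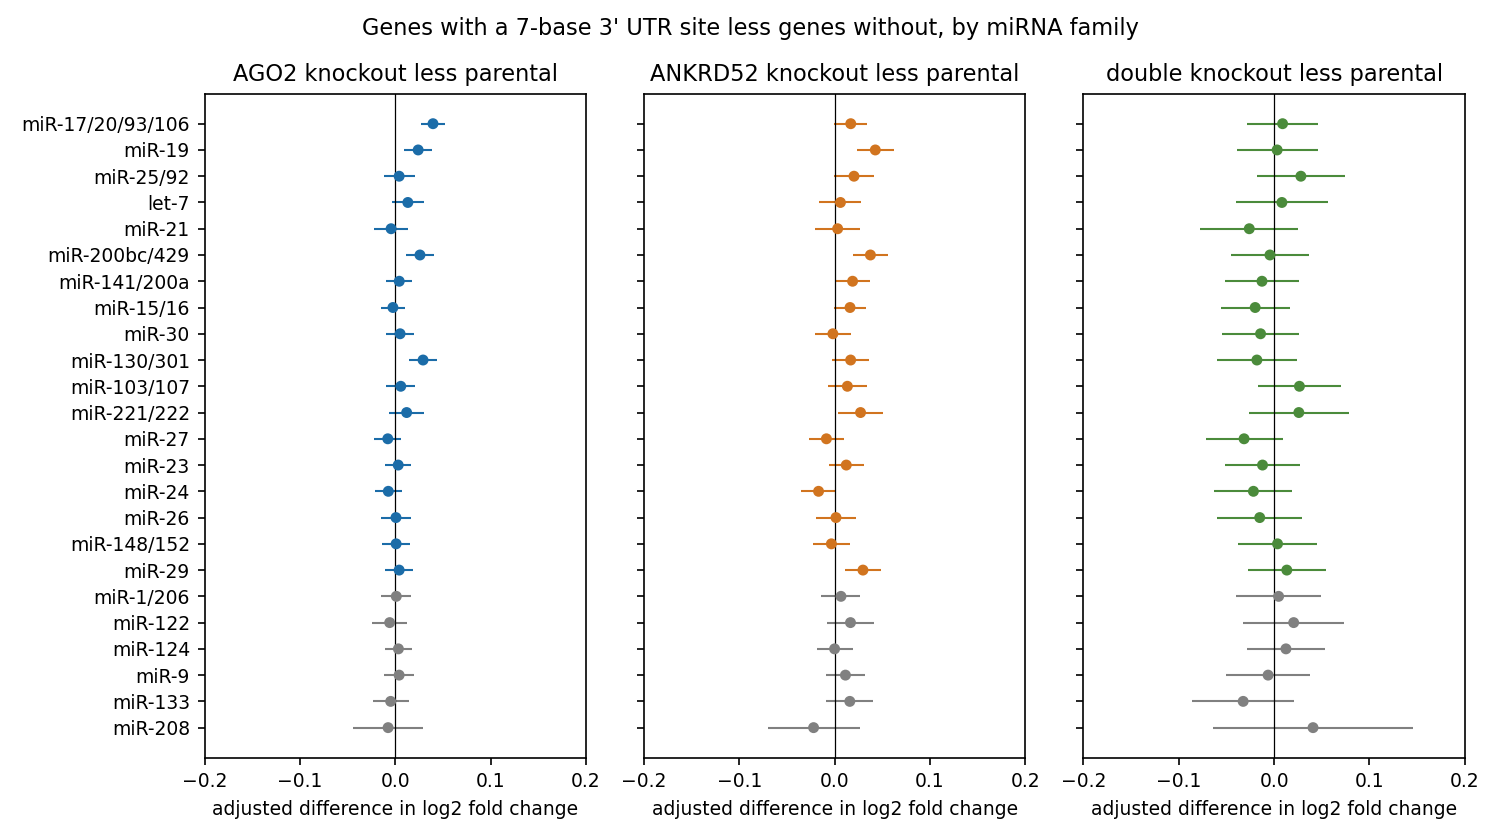
Adjusted difference in log2 fold change between genes with and without a 7-base 3' UTR site, per microRNA family (preset families in colour, control families of other tissues in grey), in each knockout less the parental line. Bars are 95% intervals across genes, and the miR-17 family lies at 0.0397 in the AGO2 knockout.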

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

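The F distribution, the limit on fold changes, leaving out chromosome 7 and distal chromosome 8, the ranking by effect and the effect averaged over all 18 families, with and without the control families subtracted, were chosen after seeing the data. No paired analysis was possible because the tables hold no per-sample values, and for the same reason leaving out replicates, other splits of the samples, other normalizations, filters on counts and other count tools were not run. A stricter adjusted p under 0.01 gave 274 genes for the AGO2 knockout, 874 for the ANKRD52 knockout and 81 rises (of 201) and 26 falls (of 114) shared by both. Adding a fold change of at least 2-fold gave 76, 242 and, for the double knockout, 1159. The F distribution gave 0 and 3 for the single knockouts (1834 and 2473 at an unadjusted p under 0.05) and 3784 for the double. It ignores the pooling of spread over genes, and the cause was not tested. A mean log2 CPM of at least 5 gave 2379 genes different between double and single and 72 shared falls, with fewer genes tested. The families in the top 1% numbered 2 with 8-base sites and 1 without covariates for the AGO2 knockout. For the ANKRD52 knockout they numbered 6 with 8-base sites (and 1 control family), 1 with 6-base sites, 1 without covariates, 8 with fold changes limited and 0 ranked by effect, and the cause was not tested. The effect averaged over all 18 families, double less ANKRD52 knockout, was -0.0161. It did not pass with 6-base sites (-0.00542) or the shortest 3' UTRs (-0.0122), though with fold changes limited it did in both (-0.00593 and -0.0160), and without covariates it reversed to 0.00446, or 0.00357 with fold changes limited, where the control families stood at 0.0222 and 0.0174. Less the control families it was -0.0180 and did not pass, and -0.0177 without covariates, -0.000687 with 8-base sites, -0.00232 with the shortest 3' UTRs, -0.0206 at a mean log2 CPM of at least 3 and -0.0194 without chromosome 7 and distal chromosome 8 did not either. It lay over 2 standard errors from 0 at -0.0212 with 6-base sites and, with fold changes limited, at -0.0157, at -0.0133 with 6-base sites, -0.0199 at a mean log2 CPM of at least 3 and -0.0173 without those chromosome parts, but not at -0.0138 without covariates (-1.99 standard errors), -0.00947 with 8-base sites or -0.0204 with the shortest 3' UTRs. The cause was not tested. The casein kinase list in the double knockout reversed from a median of 0.07, not called, to a mean of -0.69, called. It holds the targeted CSNK1A1 (-2.42) and CSNK1A1L (-2.76), which resembles it in sequence, and such large falls lower a mean more than a median. Of the other called members CSNK1G2 fell (-0.40) and CSNK1G1 rose (0.34). The list without CSNK1A1 and CSNK1A1L was not tested. Of the other values, 54 main values and 229 list and site values kept their side, and 30 list and site values lost and 7 gained it. Of those that kept it, 17 changed sign and were not called in either setting. These tallies leave out 126 values that could not move: centring shifts a list and its random lists alike and leaves p-values as they are, presence in all 3 tables removed no gene, and some lists had no member under the expression filter. They say nothing about stability. The library depths are unknown, so what depth limits was not examined.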

Other observations

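The tests of the spread of fold changes, of all 18 families, of GC content against 3' UTR length and of silencing through longer 3' UTRs, the division of chromosome 7 and the start on chromosome 8 were chosen after the results were seen. Of 4 measured intestinal genes, too few for a list test, 3 rose in the double knockout (3 adjusted over the list alone). The intestinal transcription factor CDX2 rose 6.36-fold and the mucin gene MUC13 rose by 8.87 on the log2 scale (adjusted p = 1.93e-105 and 2.65e-08) in the authors' deposited table, while in the ANKRD52 knockout they stood at -0.27 and -0.15. VIL1 of the brush border had a log2 fold change of 5.91 (adjusted p = 2.82e-38) and KRT20 of 0.52 (0.317) in the authors' deposited table. The implied level of VIL1 was under the 0.0345 CPM of 3 reads in both single knockouts (0.0243 and 0.0340 CPM). In the parental line it was 0.0485 CPM, little above that, so the size of its fold is uncertain, and 2.92 CPM in the double. Keratins KRT8 (1.53), KRT18 (1.55) and KRT19 (1.24) rose and CLDN3 (-1.74) fell there in the authors' deposited table, but the epithelial list (4 rose and 3 fell of 14, 7 adjusted over the list alone, median 0.15) was not called (adjusted p = 0.223).

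In the double knockout 10 of 16 unfolded protein and amino acid stress genes rose and 2 fell (12 adjusted over the list alone, median 0.40, adjusted p = 0.00139, or 0.180 with the mean), with ATF3 at 1.30 and XBP1 at 0.80 in the authors' deposited table, while CHAC1 stood at -1.11 in the ANKRD52 knockout and 1.42 in the double. In the ANKRD52 knockout the 3' UTR sequences with the lowest rank included GGGATTA (-0.0518, SE 0.00975), GATTACA (-0.0474) and TGAGCCA (-0.0470), which also occur in Alu repeats. In the AGO2 knockout CCACGTG, which holds the E-box sequence, lay at -0.0562 (SE 0.0107), and the AU-rich TATTTAT at 0.0341. These sequences were chosen after their values were seen. The lists of deadenylation genes, PP6 subunits, casein kinases, microRNA biogenesis genes, host transcripts, the destruction complex and NF-kB targets had no adjusted p under 0.05 in any of the 3 comparisons with the parental line. With the mean in place of the median, the NF-kB list passed in the AGO2 knockout (adjusted p = 0.0396) and the casein kinase list, which holds CSNK1A1 itself, in the double, at a mean of -0.69 against a median of 0.07 (adjusted p = 0.0132).

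In the AGO2 knockout the distal part of chromosome 8 lay low and chromosome 7 was divided. Adjustment for GC content, 3' UTR length and expression left the distal chromosome 8 median at -0.43, which argues against that trend as the whole cause. The share of its genes below 0 was 98.5%, against 84.6% in the ANKRD52 and 73.9% in the double knockout. The approximate standard errors of these genes were 1.37 times those of genes of like expression (random sets gave 0.930 to 1.06), and 1.84 and 1.32 times on both parts of chromosome 7, so 1 or 2 of the 3 replicates may carry the change. The fit shares 1 spread per gene over all 4 groups, so which libraries differ stays open, and a change in gene dosage, in a segment that holds AGO2 itself, was not tested.

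Averaged over all 18 families the site effect was 0.0129 (SE 0.00299) in the ANKRD52 knockout and -0.00320 (SE 0.00651) in the double. In the double it was over 2 standard errors above 0 with the shortest 3' UTRs and fold changes limited (0.0126, SE 0.00561; -0.00890, SE 0.0112, less the control families) and, without covariates, at 0.0743 (control families 0.0746). A larger spread in the double could hide it, and with fold changes limited to -1 to 1 the double less ANKRD52 difference of the families less the control families lay -2.16 standard errors from 0. In the other site settings with that limit it lay from -0.79 to -2.94, and some of these are within 2 standard errors, so the spread cannot be told apart from a loss of the effect. One hypothesis is that CSNK1A1 loss may restore silencing where ANKRD52 is missing, which these values leave open, and direct effects of CSNK1A1 loss on the same genes were not tested.

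Genes with longer 3' UTRs were higher in all 3 knockouts, with rank correlations across genes of 0.147, 0.238 and 0.202. GC content of 3' UTRs went with the same fold changes at -0.288, -0.177 and -0.121. With its ranks removed the length correlations were 0.0981, 0.212 and 0.184, which argues against GC as the whole cause in the ANKRD52 and double knockouts and leaves it open in the AGO2 knockout, just under the bound of 0.1. Reduced silencing through more sites could add to this and stays open, since the correlation in the double, 0.849 times that of the ANKRD52 knockout, would count against it only if silencing were restored there, which was not shown. Shared parental libraries may add to it. In the double less the ANKRD52 knockout, where they drop out, the correlation was 0.0647, between the bounds set beforehand, so this test is undecided. In the ANKRD52 less the AGO2 knockout, where they drop out too, it was 0.115, or 0.133 with GC ranks removed. No bound was set for that contrast. Its values argue against the shared libraries as the whole cause in both single knockouts together, since these differ from each other with length. They cannot tell which knockout departs from the parental line, so for either one alone the shared libraries stay open.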
